A study of Arabidopsis thaliana with 48 samples.

How the data were processed

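RNA was measured in aerial parts of 3-week-old Arabidopsis thaliana plants, per the labels' protocols, in 48 libraries made from poly(A) RNA with the TruSeq kit. The libraries form 24 groups of 2. The groups combine 3 genotypes, 2 watering regimes and 4 times of harvest. The genotypes are wild type (Columbia), gi-2, a mutant of GIGANTEA (GI), and aba1-6, a mutant of ABA1, which encodes the zeaxanthin epoxidase of abscisic acid (ABA) synthesis. Under normal watering the relative soil water content was held at 80 to 90%, and under drought at 30% from soon after germination. Plants grew in short days of 8 h light, and on the day of harvest the light was extended. Zeitgeber time (ZT) counts hours from lights on. ZT1 and ZT8 fall in the final short day, while ZT12 and ZT16 fall in the added light. Each library pooled about 50 seedlings from 3 pots, and the labels call the 2 libraries of a group biological replicates.

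The authors deposited 1 table of gene-level values for all libraries. Per the submitters' processing notes, Bowtie2, RSEM, edgeR and TAIR10 were used. Their versions, settings and roles, and whether counting used strand, are not given in the sources used here. The deposited values are expected counts (estimated counts that need not be whole), judged from the values themselves: they are not normalized, their totals differ between libraries, and 98.6% of them are whole. Among whole values of at most 10, between 66.8% and 80.2% per library were even, so part of the counts may hold both mates of a read pair as 2 counts, and no counting error is given for single values. The table has 26988 genes, of which 3329 were at 0 in every library. In the last column of the table each line ends in an extra tab, for which its unit was entered as unspecified when units were checked. Read without the extra tab, that column holds expected counts as in the other columns and was used as such. It is gi-2 under drought at ZT16, replicate 2, whose title names gi-2 and whose genotype tag names wild type. It was grouped by its title, and results were also computed without it.

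Gene names in the table were matched to the TAIR10.1 annotation by locus or symbol, and 26202 of the 26988 could be matched to 1 locus. The 786 others (3.0% of all counts) stayed in the tests under the names in the table. The annotation gave names and positions only, because the build behind the counts is named no more closely than TAIR10. Genes with close copies (KIN1 and KIN2, VSP1 and VSP2, PDF1.2 and PDF1.2c, the CBF, LHCB1, LHCB2 and RBCS genes), and genes that overlap, can share reads, so the value of a single member is uncertain.

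Expected counts were rounded to whole numbers. In R 4.3.3 with edgeR 4.0.16, genes were filtered with filterByExpr at its default settings, which left 19037, and scaled by TMM (factors from 0.862 to 1.135). Negative binomial models with 24 group means were fitted to all 48 libraries together, with robust dispersion and robust quasi-likelihood fits. This left 24 residual degrees of freedom and a biological coefficient of variation of 12.1%. Each comparison was a contrast of group means tested by the quasi-likelihood F-test, and a gene was called where the Benjamini-Hochberg adjusted p lay under 0.05. The contrasts, the lists, the rule for named genes and the alternatives were fixed before the data were examined. They are 9 contrasts averaged over the 4 times (the drought effect in each genotype, each mutant against wild type in each watering regime, and the difference of each mutant's drought effect from that of wild type), the drought effect per genotype and time, gi-2 against wild type per watering and time, and 2 tests with 3 degrees of freedom for time of day. A time-averaged log2 fold change is the mean of the log2 ratios at the 4 times. It weighs a ratio at a low level like one at a high level, so it can differ from the ratio of mean levels, which are given as CPM (a gene's counts relative to the TMM-scaled library total). Where both replicates of a group were at 0, the fitted fold change is no estimate of size and has no standard error. Where such groups lay on both sides of a time-averaged contrast, the test held no information. This applied to between 61 and 293 genes per contrast (0.3 to 1.5%), among them FT and PAP2, and 0 of them were called. Folds against 8 libraries at 0 are given as bounds, with 3 counts over those libraries as the floor.

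The 20 gene lists are ABA-induced genes, ABA synthesis, catabolism and transport, ABA receptors and SnRK2 kinases, DREB/CBF and early dehydration genes, proline and raffinose-family osmolytes, circadian clock, photoperiodic flowering, PIF factors and PIF-regulated growth genes, flavonoid and anthocyanin synthesis, photosynthesis, starch metabolism, carbon starvation and darkness, salicylic acid and defence, jasmonic acid, aliphatic glucosinolate synthesis, heat shock, root markers, guard cell markers, floral organ and meristem markers, and reference genes. Each list was compared with all other tested genes by camera in limma 3.58.1, with a preset correlation of 0.01 between genes. The adjusted p runs over the 20 lists of a contrast. The same test with a correlation estimated from the residuals and the self-contained test fry were alternatives. Members were also counted with the p adjusted over the list alone. The genes named are GI and ABA1 in every group. Per time-averaged contrast the rule adds 8 genes higher and 8 lower with the largest absolute fold changes among those called, with a mean of at least 5 CPM in the higher group and the same sign at all 4 times. Members of the lists could be named freely.

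Calls common to both mutants were compared with chance, because both use the same wild-type libraries. Chance was taken from 100 simulated pairs of unchanged mutants against those libraries, and from the product of the numbers of calls divided by the number of genes. The wild-type libraries were also split by replicate number. Alternatives for every count were DESeq2 size factors, library totals as the only scaling, no filter on low counts, a filter at a mean of 5 CPM, DESeq2 1.42.0 as the test, only the libraries of the groups compared, the replicate number as a block, and leaving out each library in turn, where the lone library left in a group was assumed to vary like the other groups. Added after seeing the data were a block per genotype and a fit without the 2 shallowest libraries.

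Replicate numbers come from the titles, which give no shared batch or day. Deviations from group means were correlated for same-numbered libraries. Within wild type all 28 pairs of groups had a correlation above 0.1 (median 0.31, from 0.15 to 0.51), so there the numbers paired the libraries. In gi-2 it was 6 of 28 pairs (median 0.02) and in aba1-6 8 of 28 (median 0.05), and between genotypes the medians lay between -0.03 and 0.03. The numbers therefore paired libraries in wild type and not across genotypes.

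The procedure was tested on simulated counts for the 19037 genes, with 200 genes changed, all at a mean of at least 5 CPM. Counts were drawn independently, with the same spread for a gene in every group. Differences in spread between groups, the shared deviations of wild-type libraries and changes in many more genes were left out. The shares below may therefore not hold for the real libraries. For the time-averaged drought effect in wild type it recovered 86.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, and 9 of 199 calls were false. At ZT1 alone the shares were 31.3%, 79.1% and 97%. For the difference of the drought effect between gi-2 and wild type they were 56.7%, 94% and 97%, with 10 of 175 calls false. Quality checks and plots were made in Python with numpy 2.4.6 and matplotlib.

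Total counts per library ran from 1920012 to 26925706. The shallowest were wild type under normal watering at ZT12, replicate 1, and wild type under drought at ZT16, replicate 2 (2289812). The 10 most abundant genes took 5.06 to 9.32% of the counts. Replicates of a group correlated across 14650 genes at 0.9505 to 0.9928 on the log2(CPM + 1) scale. Their counts differed by 3.0 to 13.8 times the variance of sampling noise, taken as if every count were a separate molecule. Where both mates of a pair were counted, that noise is larger and the multiples are lower. No 2 libraries of a group held identical counts, and each was used as 1 replicate.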

Results

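Transcript levels were measured in 48 libraries from the aerial parts of Arabidopsis plants of 3 genotypes, grown with normal watering or under a constant water deficit and harvested at ZT1, ZT8, ZT12 and ZT16. The series title presents GI as a repressor of transcriptional responses to ABA, and the design asks how the drought response of gi-2 and of the ABA-deficient aba1-6 compares with that of wild type. Each combination of genotype, watering and time had 2 libraries, so 8 libraries stood behind each time-averaged level. In wild type the same-numbered libraries deviated together across times, and the fit had no term for this. Standard errors and p-values of a time-averaged mutant against wild type may therefore be too small. For the drought effect in wild type, and for differences from it, such deviations cancel in the contrast but stay in the fitted spread. Standard errors and p-values there may be too large. Total counts ranged from 1920012 to 26925706 per library, and 19037 genes were tested. Time of harvest separated the libraries most: the 2 leading principal components held 39.3% and 16.1% of the variance, of which time accounted for 96.8% and 71.3%. The next component (10.3%) separated genotypes (64.3% of it) and watering (27.7%).

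GI, which encodes a nuclear protein of the circadian clock and of photoperiodic flowering, lies on chromosome 1 at 8061751 to 8067790 (TAIR10.1). Its transcript was present in gi-2 and had another daily course there. In wild type under normal watering GI stood at 72.5 ± 6.68 CPM at ZT1, 300.6 ± 6.86 at ZT8, 63.4 ± 2.72 at ZT12 and 12.5 ± 1.8 at ZT16 (mean ± SD, n = 2). In gi-2 the same times gave 35.7 ± 2.81, 140.1 ± 8.49, 104 ± 6.59 and 52 ± 0.75 CPM. In aba1-6 they gave 40.5, 287.2, 42.8 and 9.6 CPM, so at ZT1 that mutant lay below wild type as well. The gi-2 level was thus lower at ZT1 and ZT8 (log2 fold change -1.02 and -1.10, edgeR adjusted p = 3.44e-05 and 4.17e-06) and higher at ZT12 and ZT16 (0.70 and 2.05, edgeR adjusted p = 0.00374 and 1.52e-11). Without the wild-type ZT12 replicate 2 or the gi-2 ZT12 replicate 1 library, the ZT12 difference did not pass (edgeR adjusted p = 0.055 and 0.0619). Averaged over the day it did not pass the test (log2 fold change 0.16, edgeR adjusted p = 0.222). Under drought gi-2 held 52.5, 161, 112.4 and 55.2 CPM at the 4 times, against 81.3, 279.2, 76.2 and 18.3 CPM in wild type. The library whose title names gi-2 and whose genotype tag names wild type belongs to the gi-2 drought group at ZT16, whose 55.2 ± 1.31 CPM (SD, n = 2) lay far from the wild-type value.

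ABA1 (zeaxanthin epoxidase, chromosome 5, 26753469 to 26757402) also kept its transcript in its own mutant. In aba1-6 under normal watering it stood at 584.8 ± 36.6 CPM at ZT1, against 713.2 ± 55.6 CPM in wild type (SD, n = 2), so its level does not check the genotype labels. The time-averaged log2 fold change in aba1-6 was -0.25 under normal watering (edgeR adjusted p = 0.0602) and -0.29 under drought (edgeR adjusted p = 0.017). In gi-2, ABA1 was higher than in wild type in both regimes in the mean of log2 ratios (log2 fold change 0.70 ± 0.09 SE under normal watering, edgeR adjusted p = 4.42e-07). It was not higher at ZT1, where its level peaked: gi-2 held 661.8 against 713.2 CPM under normal watering and 694.5 against 857.3 CPM under drought. At ZT12 gi-2 held 209.7 ± 8.06 CPM of it and wild type 81.8 CPM, and at ZT16 235.6 ± 8.13 and 121.8 CPM (SD, n = 2).

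**Figure D1:**
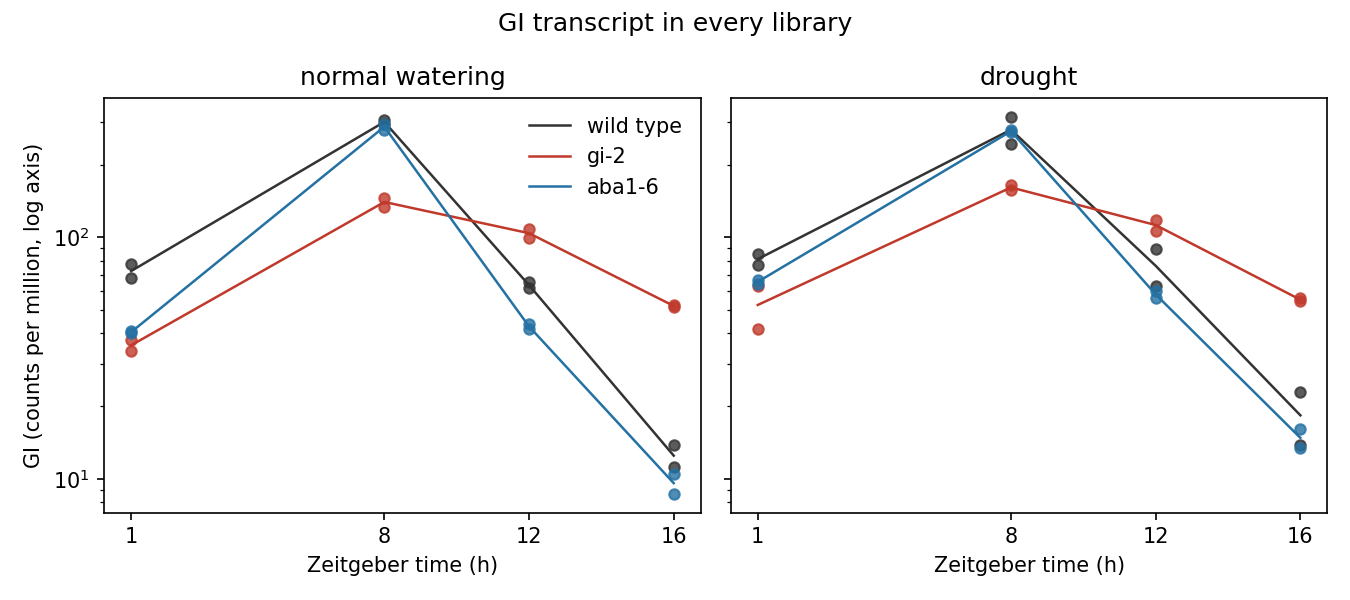
GI transcript level (CPM, log axis) against Zeitgeber time (hours) under normal watering and drought in wild type, gi-2 and aba1-6; points are libraries and lines join the means of 2. The gi-2 line lies below the others at ZT1 and ZT8 and above them at ZT12 and ZT16, where it held 52 CPM against 12.5 in wild type under normal watering.

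Across the day, 7279 genes changed in wild type under normal watering by the edgeR test with 3 degrees of freedom. The morning gene LHY fell from 538.8 CPM at ZT1 to 0.623 at ZT8, and the evening gene TOC1 rose from 8.49 to 186.2 CPM (edgeR adjusted p = 7.69e-29 and 1.82e-23). The drought effect in wild type itself differed between times for 156 genes, with 249 without the drought ZT16 replicate 1 library and 520 with the replicate number as a block within each genotype. With only the compared libraries in the fit it was 16.

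Drought in wild type raised transcripts of ABA-responsive protection and signalling genes. LTI65 (also called RD29B, a desiccation-related protein) went from 8.15 to 93.2 CPM (log2 fold change 4.54 ± 0.77 SE, edgeR adjusted p = 7.62e-05). HAI2, a clade A protein phosphatase that acts against ABA signalling, went from 2.62 to 31.2 CPM (3.67 ± 0.21, edgeR adjusted p = 9.23e-16), and its relative PP2CA from 67.1 to 191 CPM (1.45 ± 0.09). RD29A and the dehydrin gene ERD10 rose likewise (1.45 ± 0.12 and 1.37 ± 0.08). So did NCED3, which encodes the key ABA synthesis enzyme under water deficit (6.21 to 14 CPM, 1.14 ± 0.15). Of the 35 measured ABA-induced genes, 30 rose and 1 fell, or 31 and 1 adjusted over the list alone, with a median log2 fold change of 1.14 (camera adjusted p = 8.02e-52). The member that fell was ANAC019, a NAC transcription factor (9.27 to 1.74 CPM).

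In all, 4371 genes changed with drought in wild type, 1948 of them higher and 2423 lower (44.6% higher, or 54.9% with library totals as the only scaling). With only the compared libraries in the fit the count was 2444. Among genes with the largest rises were AT4G08570 (0.37 to 11.98 CPM), the Nudix hydrolase gene NUDT24 (0.73 to 17.47 CPM), AT2G37870 (0.82 to 20.61 CPM, log2 fold change 4.68 ± 0.47 SE), the heat shock factor HSFA6A (0.62 to 6.55 CPM), DAA1 (3.56 to 34.53 CPM) and the seed-protein gene LEA4-5 (1.9 to 12.53 CPM). Among genes with the largest falls, the defensin gene PDF1.2 was at 0 counts in all 8 drought libraries and at least 120-fold lower than under normal watering, and DXPS1 at least 140-fold lower. ELI3-2 fell from 23.02 to 0.21 CPM, and the lipid-transfer-like genes pEARLI_1 and AT4G12490 fell from 27.05 to 0.09 and from 12.49 to 0.10 CPM.

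All 13 measured flavonoid and anthocyanin synthesis genes rose with drought in wild type (13 adjusted over the list alone, median 1.54, camera adjusted p = 7.86e-17). DFR, an enzyme of the anthocyanin branch, went from 46 to 159 CPM, UGT75C1, an anthocyanin glucosyltransferase, from 34.1 to 113 CPM, and the regulator TT8 from 3.97 to 16.5 CPM. Starch genes rose in part (5 of 12, 6 adjusted over the list alone, camera adjusted p = 0.000212), led by APL3, a subunit of the starch synthesis enzyme ADP-glucose pyrophosphorylase (66.2 to 181 CPM). That list's adjusted p = 0.376 with an estimated correlation. Carbon starvation and darkness genes fell (4 of 6, 4 adjusted over the list alone, median -1.84, camera adjusted p = 1.05e-05), among them DIN11 (log2 fold change -3.95 ± 0.59 SE) and the beta-galactosidase gene BGAL4 (13.7 to 3.4 CPM). ABA receptor and SnRK2 genes fell (6 of 12, 6 adjusted over the list alone, median -0.28, camera adjusted p = 0.00126, adjusted p = 0.066 with an estimated correlation). The receptor gene PYL4 went from 22.5 to 6.37 CPM and PYL8 from 43.4 to 27.5 CPM. The clock list did not pass (3 of 21 rose and 1 fell, 4 and 2 adjusted over the list alone, camera adjusted p = 0.667), and its median of -0.08 and mean of -0.04 were negative while the test pointed up. The photoperiodic flowering list did not pass either (4 of 16 rose and 1 fell, 4 and 2 adjusted over the list alone, camera adjusted p = 0.396). Within it, SOC1, a promoter of flowering, rose from 10 to 16.3 CPM and TEM2, a repressor of it, fell (-1.48 ± 0.20). The DREB/CBF list gave 2 of 11 higher (3 and 1 lower adjusted over the list alone), with a median of -0.05, a mean of 0.10 and a test pointing up (camera adjusted p = 0.396). ERD14, a dehydrin gene in it, went from 280 to 506 CPM.

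Root markers, which stand for a tissue that was not harvested, fell with drought in wild type (2 of 4 measured members, 3 adjusted over the list alone, median -2.51, camera adjusted p = 0.0179, adjusted p = 0.33 with an estimated correlation). That call was lost with a replicate block within each genotype (camera adjusted p = 0.0529), without the filter on low counts (0.133), with a filter at 5 CPM (0.0915) and without the 2 shallowest libraries (0.0738). It was also lost without wild-type drought ZT1 replicate 1 (0.057), ZT12 replicate 2 (0.0629) or ZT16 replicate 1 (0.064). Salicylic acid and defence genes were lower (4 of 16, 4 adjusted over the list alone, median -0.235, camera adjusted p = 0.0203, adjusted p = 0.465 with an estimated correlation). Their camera adjusted p was 0.0529 with a replicate block within each genotype, 0.0517 with the filter at 5 CPM and 0.0839 without wild-type drought ZT16 replicate 1. Photosynthesis genes were lower too (8 of 23, 9 adjusted over the list alone, median -0.16, camera adjusted p = 0.0039, adjusted p = 0.637 with an estimated correlation), with a camera adjusted p of 0.0745 without wild-type drought ZT12 replicate 2 and 0.141 without the 2 shallowest libraries. Of the proline and raffinose-family genes, 5 of 12 rose and 2 fell (7 and 3 adjusted over the list alone, median 0.26, camera adjusted p = 0.00869, adjusted p = 0.376 with an estimated correlation), with a camera adjusted p of 0.0563 without wild-type normal ZT1 replicate 2.

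In gi-2, drought changed 984 genes, 312 higher and 672 lower (31.7% higher). The count was 642 without the gi-2 drought ZT8 replicate 1 library and 648 without gi-2 drought ZT12 replicate 2. It was 1615 with a replicate block within each genotype and 1995 with only the compared libraries in the fit, against 2444 in wild type and 2533 in aba1-6 fitted that way. The fit of all libraries shares its estimate of each gene's spread across groups, and the gap between genotypes in these counts depended on the fit. Among ABA-induced genes, KIN1, which has a close copy, rose from 13.33 to 29.3 CPM (log2 fold change 1.28 ± 0.33 SE, edgeR adjusted p = 0.0217). Its call was lost without any 1 of 7 libraries, which were replicate 2 of gi-2 normal ZT1, ZT8, ZT12 and ZT16, replicate 1 of gi-2 drought ZT1 and ZT8 and gi-2 drought ZT16 replicate 2 (edgeR adjusted p up to 0.0889, without the last). HAI2 rose from 3.93 to 7.75 CPM (0.84 ± 0.21, edgeR adjusted p = 0.0113, lost without gi-2 drought ZT8 replicate 1 or gi-2 drought ZT1 replicate 1, at most to 0.116 without the latter). RD29A went from 608 to 741 CPM (log2 fold change 0.29 ± 0.12 SE, edgeR adjusted p = 0.153), PP2CA from 76.6 to 91.1 CPM (0.26 ± 0.09, edgeR adjusted p = 0.088) and NCED3 from 6.23 to 7.15 CPM (0.18, edgeR adjusted p = 0.597). GOLS2, which encodes a galactinol synthase of raffinose-family sugars, rose from 41.5 to 64.4 CPM (0.63 ± 0.12, edgeR adjusted p = 0.00154), and RD22 rose from 942 to 1280 CPM. Of the 35 measured genes, 8 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 1.32e-07, adjusted p = 0.246 with an estimated correlation). By replicate number, the mean rise of the list on the log2(CPM + 1) scale was 0 in replicate 1 and 0.42 in replicate 2, although the numbers did not pair libraries in gi-2. Rises outside that list included those of FSD1, a superoxide dismutase gene (144.77 to 325.37 CPM), CPUORF47 (88.35 to 183.57 CPM) and AT3G53400 (48.34 to 99.71 CPM).

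Genes lower under drought in gi-2 included SAG13, a senescence-associated gene (16.2 to 0.41 CPM, log2 fold change -4.75 ± 0.64 SE), AT4G12490 (8.84 to 0.10 CPM) and ANAC019 (6.1 to 0.605 CPM). Carbon starvation genes fell here too (3 of 6, 4 adjusted over the list alone, median -1.57, camera adjusted p = 6.6e-06), and starch genes rose (4 of 12, 7 adjusted over the list alone, median 0.22, camera adjusted p = 1.21e-07, adjusted p = 0.154 with an estimated correlation). The flavonoid list had a median of 0.67 with 2 of 13 genes higher (11 adjusted over the list alone, camera adjusted p = 2e-09, adjusted p = 0.071 with an estimated correlation), one of them F3H (49.2 to 66.5 CPM). Salicylic acid and defence genes fell by 0.26 in the median (2 of 16, 7 adjusted over the list alone, camera adjusted p = 0.000102, adjusted p = 0.239 with an estimated correlation). The root marker list fell in gi-2 as well (3 of 4 measured members, 4 adjusted over the list alone, median -1.93, camera adjusted p = 1.32e-07), although hypocotyl and roots were not harvested. Its drought effect did not differ by the test from that in wild type (camera adjusted p = 0.855). Its member NRT2.1, a nitrate transporter gene, fell in every genotype, from 12.9 to 0.846 CPM in wild type, 12.4 to 1.45 in gi-2 and 16.5 to 2.58 in aba1-6.

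In the ABA-deficient aba1-6, ABA-induced genes rose with drought. LTI65 went from 0.685 to 26.6 CPM (log2 fold change 5.40 ± 0.93 SE, edgeR adjusted p = 0.000291), the cold-regulated gene COR15A from 93.3 to 262 CPM (1.65 ± 0.15) and RD29A from 204 to 371 CPM (1.18 ± 0.12). PP2CA went from 28.2 to 53.5 CPM (0.92 ± 0.10) and NCED3 from 10.9 to 26.6 CPM (1.45 ± 0.13), against a normal level of 6.21 CPM in wild type. Of the 35 genes, 26 rose (31, and 1 lower, adjusted over the list alone), with a median of 0.83 (camera adjusted p = 8.88e-54). Drought changed 1775 genes in aba1-6, 764 higher and 1011 lower. Further large changes were a rise of LTP3, a lipid transfer protein gene (7.12 to 47.11 CPM), and falls of AT4G12490 (11.16 to 0.51 CPM) and SAG13 (12.95 to 0.50 CPM). Starch genes rose (5 of 12, 5 adjusted over the list alone, median 0.18, camera adjusted p = 2.29e-08, adjusted p = 0.124 with an estimated correlation). Carbon starvation genes fell (3 of 6, 3 adjusted over the list alone, median -0.87, camera adjusted p = 0.000231, adjusted p = 0.072 with an estimated correlation). Receptor and SnRK2 genes fell (6 of 12, 6 adjusted over the list alone, median -0.22, camera adjusted p = 3.01e-06). Flavonoid genes rose (6 of 13, 9 adjusted over the list alone, median 0.60, camera adjusted p = 3.42e-05, adjusted p = 0.228 with an estimated correlation). Root markers fell (2 of 4, 2 adjusted over the list alone, median -1.78, camera adjusted p = 0.00155, adjusted p = 0.124 with an estimated correlation).

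Tested directly, the drought effect differed between gi-2 and wild type for 1325 genes, 737 with a higher and 588 with a lower log2 fold change in gi-2 (55.6% higher, or 41.2% with library totals as the only scaling). Without the wild-type drought ZT16 replicate 1 library the count was 2006, and with a replicate block within each genotype it was 2678. Of the 35 ABA-induced genes, 25 had a smaller drought effect in gi-2 (28 adjusted over the list alone), with a median difference of -0.99 (camera adjusted p = 3.42e-39). The difference was -2.83 ± 0.30 SE for HAI2, -2.24 ± 0.56 for HAI1, -2.14 ± 0.28 for AFP1, a binding protein of the ABA response factor ABI5, -1.19 ± 0.13 for PP2CA, -1.15 ± 0.16 for RD29A and -0.95 ± 0.22 for NCED3. GASA1, a gibberellin-regulated gene, fell from 85.8 to 13.7 CPM in wild type and stood at 70.35 and 74.3 CPM in gi-2. XTH6, a cell wall gene, fell from 176.76 to 64.63 CPM in wild type and stood at 156.16 and 151.37 CPM in gi-2. PYL4 (1.25 ± 0.25) and RBCS1B, a Rubisco small subunit gene with close copies (0.58 ± 0.11), likewise fell in wild type and had a higher log2 fold change in gi-2.

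**Figure D2:**
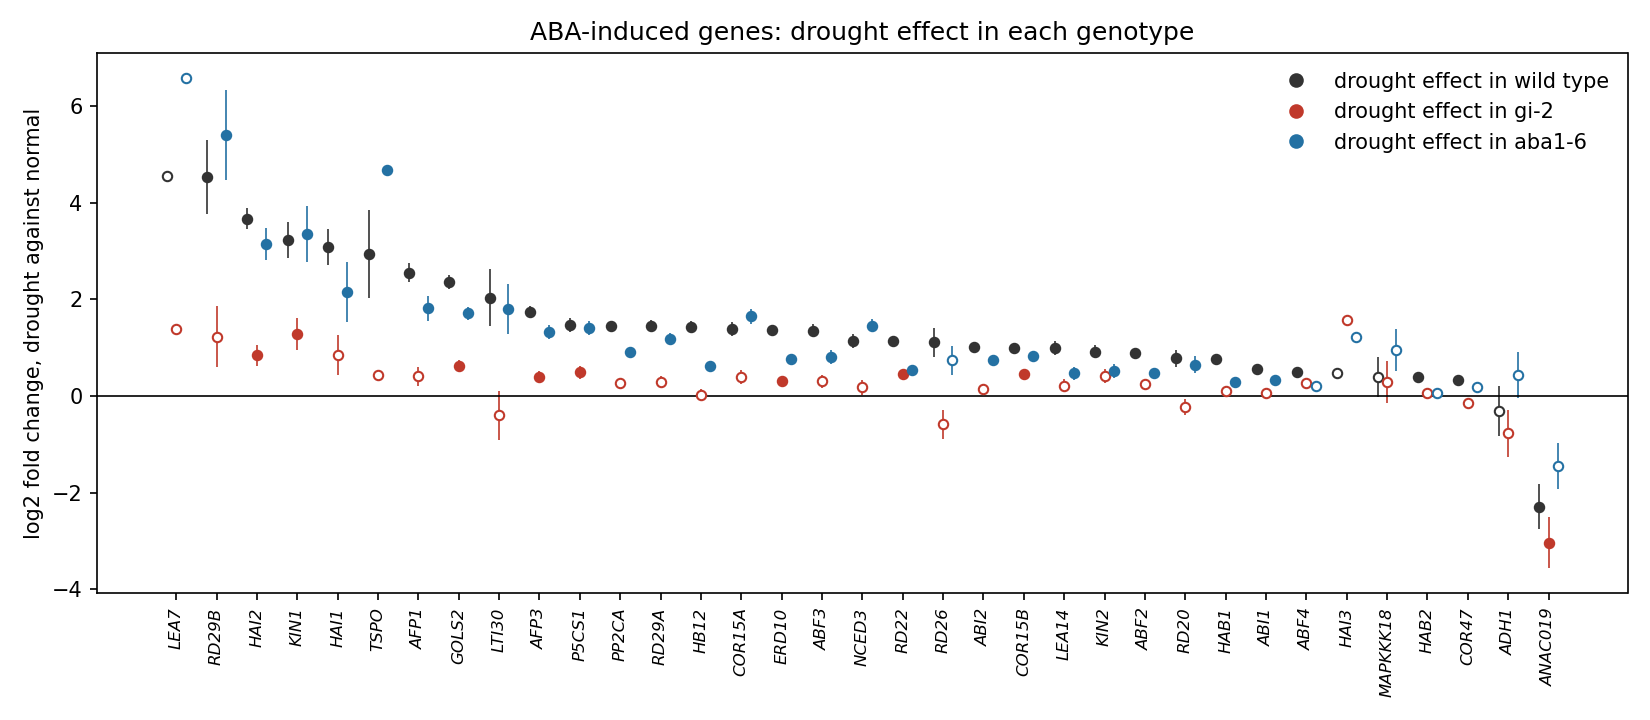
Log2 fold change (drought against normal watering, mean of 4 times) of the 35 measured ABA-induced genes in wild type, gi-2 and aba1-6; filled points passed the edgeR test, open points did not, and bars are SE, left out where a group was at 0. Medians were 1.14 in wild type, 0.29 in gi-2 and 0.83 in aba1-6.

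Between aba1-6 and wild type the drought effect differed for 522 genes, 348 with a higher and 174 with a lower log2 fold change in aba1-6. This count was 1510 with a replicate block within each genotype, 998 without the filter on low counts and 305 with only the compared libraries in the fit. It moved with single libraries: 309 without wild-type drought ZT1 replicate 2, 347 without aba1-6 drought ZT8 replicate 1, 792 without wild-type normal ZT12 replicate 2 and 833 without wild-type drought ZT16 replicate 1. For ABA-induced genes the median difference was -0.27, with 7 of 35 lower (11 adjusted over the list alone, camera adjusted p = 1.13e-06, adjusted p = 0.687 with an estimated correlation). The flavonoid list had a median difference of -0.91, with 2 of 13 genes lower (11 adjusted over the list alone, camera adjusted p = 1.68e-10, adjusted p = 0.188 with an estimated correlation). UGT75C1 went from 27.1 to 42.8 CPM in aba1-6, a difference of drought effects of -0.97 ± 0.20 (SE) (edgeR adjusted p = 0.00518).

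Under normal watering gi-2 had higher levels of several ABA- and dehydration-related genes than wild type. RD29A was higher (608 against 481 CPM, log2 fold change 0.89 ± 0.12 SE, edgeR adjusted p = 1.47e-06), as were COR15A (852 against 482 CPM, 1.03 ± 0.14), GOLS2 (41.5 against 19.2 CPM, 1.27 ± 0.14) and P5CS1 of proline synthesis (479 against 263 CPM, 0.89 ± 0.14). Of the 35 ABA-induced genes, 10 were higher (12 adjusted over the list alone, median 0.30, camera adjusted p = 1.49e-09, adjusted p = 0.194 with an estimated correlation). In all, 2419 genes differed, 1351 higher and 1068 lower. Among the genes with the largest differences were higher levels of the cold-responsive galactinol synthase gene GolS3 (10.45 against 4.41 CPM), the lipid-transfer-like AZI1 (40.69 against 8.66 CPM), QQS (9.57 against 1.99 CPM) and the cell wall gene XTH17 (10.86 against 2.93 CPM). Lower levels were those of HEI10, a meiotic recombination gene that overlaps MRD1 and can share its reads (1.64 against 26.31 CPM, -4.15 ± 0.14), BT2 (8.69 against 38.17 CPM) and the flavonol regulator MYB111 (1.75 against 11.4 CPM).

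Clock genes stood apart in gi-2 under normal watering: 11 of 21 were higher and 3 lower (12 and 4 adjusted over the list alone, median 0.29, camera adjusted p = 9.07e-12). PRR7, a repressor of morning genes, had a log2 fold change of 1.3 ± 0.08 (SE), its relative PRR9 2.06 ± 0.25, and LNK1 1.06 ± 0.06. LHY was lower (-1.28 ± 0.33). Without the wild-type normal ZT12 replicate 2 library its fitted value was 0.24, but that group was then at 0 counts, so this is no estimate of size. At the 4 times LHY stood at 324.4, 1.2, 0.136 and 1.1 CPM in gi-2. In wild type it stood at 538.8, 0.623, 0.446 and 11.3 CPM. PIF and growth genes were higher (5 of 13, 6 and 1 lower adjusted over the list alone, median 0.26, camera adjusted p = 1.49e-09), led by PIF4, a light-regulated growth factor (113 against 80.1 CPM, 1.24 ± 0.07), and HFR1, a repressor of PIF proteins (16.4 against 7.28 CPM). Photosynthesis genes were higher in the mean of log2 ratios (13 of 23, with 3 lower, 14 and 4 adjusted over the list alone, median 0.47, camera adjusted p = 2.68e-26). The antenna gene LHCB2.2, which has close copies, had a log2 fold change of 1.83 ± 0.13, while its mean levels were 1060 and 1010 CPM, since the ratio was large where levels were low. Heat shock genes were lower in the test (1 of 7, 2 adjusted over the list alone, median -0.49, camera adjusted p = 0.00738), with HSP101 at 12.8 against 22.6 CPM. FT, the mobile flowering signal, was at 0 counts in all gi-2 libraries and at least 27-fold lower than in wild type under normal watering. In wild type it was also at 0 at ZT1 and ZT8, and stood at 1.02 and 3.22 CPM at ZT12 and ZT16. Its time-averaged test held no information, and FT was not called. The photoperiodic flowering list as a whole did not pass (3 of 16 higher and 4 lower, 3 and 4 adjusted over the list alone, camera adjusted p = 0.262).

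Under drought 5460 genes differed between gi-2 and wild type, 2919 higher and 2541 lower in gi-2 (53.5% higher, or 38.4% with library totals as the only scaling). ABA-induced genes were lower in gi-2 (22 of 35, with 1 higher, 23 and 1 adjusted over the list alone, median -0.62, camera adjusted p = 2.09e-11, adjusted p = 0.121 with an estimated correlation). HAI1 stood at 7.45 against 47.2 CPM (log2 fold change -2.61 ± 0.34 SE, edgeR adjusted p = 2.1e-06), PP2CA at 91.1 against 191 CPM (-1 ± 0.09, edgeR adjusted p = 5.26e-11) and AFP1 at 10.3 against 37.2 CPM (-1.71 ± 0.18, edgeR adjusted p = 1e-08). Clock genes (13 of 21 higher and 3 lower, 13 and 3 adjusted over the list alone, median 0.43, camera adjusted p = 8.6e-08) and PIF genes (5 of 13 higher and 2 lower, 6 and 3 adjusted over the list alone, median 0.86, camera adjusted p = 0.000128) were again higher in their tests. Photosynthesis genes were also higher (16 of 23, 17 adjusted over the list alone, median 0.60, camera adjusted p = 1.51e-20, adjusted p = 0.0568 with an estimated correlation). Heat shock genes were lower (3 of 7, 3 adjusted over the list alone, median -0.83, camera adjusted p = 0.00807), with HSP70 at 40.1 against 124 CPM. Large single differences were those of AZI1 (34.23 against 1.46 CPM), the purine permease gene PUP18 (19.53 against 4.6 CPM), RVE2, a clock-related gene (3.53 against 89.84 CPM), HEI10 (1.73 against 32.48 CPM) and APL3 (65.1 against 181 CPM). SOC1 was lower in gi-2 (9.65 against 16.3 CPM).

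Flavonoid genes were lower in gi-2 in both watering regimes. Of 13 measured, 11 were lower under normal watering (11 adjusted over the list alone, median -1.51, camera adjusted p = 2.68e-26) and 13 under drought (13 adjusted over the list alone, median -2.24, camera adjusted p = 1.02e-34). Chalcone synthase (CHS, also TT4), the entry enzyme of the pathway, stood at 53.6 against 353 CPM under normal watering and 68.8 against 512 CPM under drought (log2 fold change -2.27 ± 0.20 and -2.37 ± 0.19 SE, edgeR adjusted p = 9.54e-09 and 3.62e-10). DFR stood at 21.3 against 159 CPM under drought (-2.39 ± 0.26), and the flavonol synthase gene FLS1 had a log2 fold change of -1.73 ± 0.15 and -2.08 ± 0.14 in the 2 regimes. In aba1-6 the list was lower under drought (12 of 13, 13 adjusted over the list alone, median -1.21, camera adjusted p = 9.79e-14). Under normal watering 3 of 13 were lower (3 adjusted over the list alone, median -0.28, camera adjusted p = 0.0969, but 0.0449 without the filter on low counts).

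**Figure D3:**
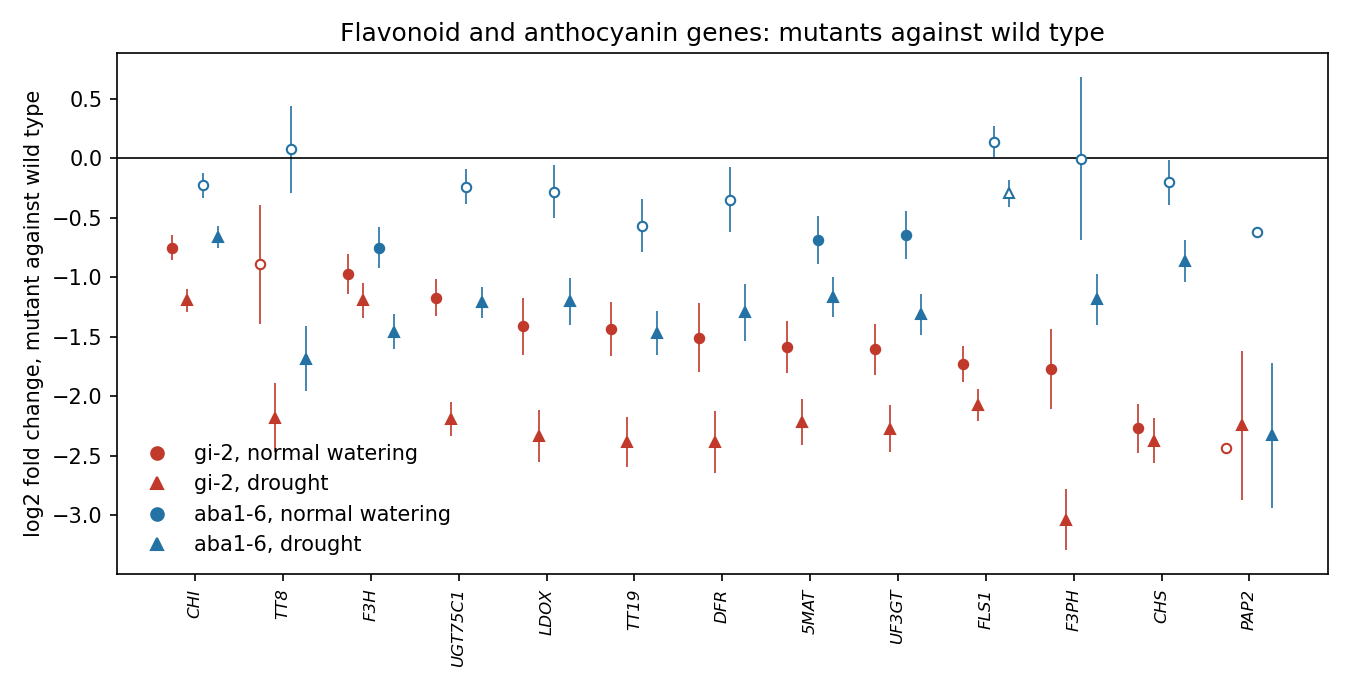
Log2 fold change against wild type (mean of 4 times) of 13 flavonoid and anthocyanin synthesis genes in gi-2 and aba1-6 under normal watering (circles) and drought (triangles); filled points passed the edgeR test, open points did not, and bars are SE. Medians in gi-2 were -1.51 and -2.24, and in aba1-6 -0.28 and -1.21.

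The mutant aba1-6 had lower levels of ABA-induced genes than wild type in both regimes. COR15A stood at 93.3 against 482 CPM under normal watering (log2 fold change -2.84 ± 0.15 SE, edgeR adjusted p = 2.17e-13) and 262 against 1360 CPM under drought (-2.58 ± 0.15, edgeR adjusted p = 1.83e-13). Of 35 ABA-induced genes, 20 were lower and 1 higher under normal watering (21 and 1 adjusted over the list alone, median -0.825, camera adjusted p = 4.34e-28). Under drought 27 were lower and 1 higher (27 and 1 adjusted over the list alone, median -0.99, camera adjusted p = 7.68e-47). Of the ABA hydroxylase genes, CYP707A2 was lower in both regimes (log2 fold changes of -2.79 ± 0.33 and -3.54 ± 0.27), as were CYP707A1 (-1.84 and -1.87) and CYP707A4 (-1.77 and -3.2). CYP707A3 did not pass (-0.19 and -0.39, edgeR adjusted p = 0.72 and 0.367). The glucosidase gene BG1, whose product releases ABA from its conjugate, stood at 347 against 1320 and 311 against 1780 CPM, and NCED3 was higher (0.61 ± 0.15 and 0.92 ± 0.13). The ABA synthesis, catabolism and transport list thus went both ways (5 of 15 higher and 4 lower under normal watering, 5 and 5 adjusted over the list alone), with a median of 0.04, a mean of -0.36 and a test pointing down (camera adjusted p = 0.328). Receptor and SnRK2 genes were higher (9 of 12 in each regime, 10 adjusted over the list alone in each, medians 0.44 and 0.36, camera adjusted p = 1.44e-11 and 2.42e-09), with PYL4 at 54.3 against 22.5 CPM under normal watering. Jasmonic acid genes were lower (7 of 14 under normal watering, 8 adjusted over the list alone, median -0.52, camera adjusted p = 1.57e-06, adjusted p = 0.323 with an estimated correlation). Under drought 8 of 14 were lower (8 adjusted over the list alone, median -0.65, camera adjusted p = 5.8e-05, adjusted p = 0.28 with an estimated correlation). The vegetative storage protein gene VSP2, which has a close copy, stood at 13.2 against 142 CPM under normal watering, and AOS of jasmonate synthesis at 251 against 538 CPM. In gi-2 against wild type the jasmonic acid list was also lower by camera, with medians of -0.417 under normal watering and -0.497 under drought. Those calls were lost with an estimated correlation (camera adjusted p = 0.371 and 0.607), and the drought call also with library totals as the only scaling (0.0646).

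Against wild type, aba1-6 differed for 3231 genes under normal watering (1455 higher and 1776 lower, 45% higher, or 66.9% with library totals as the only scaling) and for 4310 under drought (2161 higher and 2149 lower, 50.1% higher, or 63.4% with library totals). The highest ratio was that of AT3G01345 (chromosome 3, 129138 to 130749), at 262.24 against 0.23 CPM under normal watering and 240.6 against 0.22 CPM under drought. CRK30, a receptor-like kinase gene, stood at 25.55 against 1.8 CPM and AT1G27020 at 40.74 against 5.95 CPM under normal watering. MBP1, a myrosinase-binding protein gene, stood at 24.36 against 404.05 CPM under normal watering and 26.22 against 675.11 CPM under drought, and AT3G27250 at 0.31 against 8.59 CPM and 4.55 against 56.44 CPM. Of 3 measured floral organ and meristem markers, which stand for other tissues, 2 were higher in aba1-6 in each regime (2 adjusted over the list alone in each), with medians of 1.68 under normal watering (camera adjusted p = 0.113, but 0.0449 without the filter on low counts and 0.048 without aba1-6 normal ZT1 replicate 2) and 1.81 under drought (camera adjusted p = 0.181). With fry this list passed in both regimes (fry adjusted p = 0.00134 and 0.00041). The 2 markers that were higher were PI (2.27 against 0.866 and 2.58 against 0.77 CPM) and SEP3 (0.798 against 0.226 and 0.517 against 0.15 CPM). Under normal watering both calls were lost without aba1-6 normal ZT1 replicate 1 (edgeR adjusted p = 0.0758 and 0.0837), and that of SEP3 also without aba1-6 normal ZT8 replicate 2 (0.059). Under drought that of SEP3 was lost without wild-type drought ZT16 replicate 1 (edgeR adjusted p = 0.0531).

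By time of day, drought changed 1201, 1244, 1165 and 704 genes in wild type at ZT1, ZT8, ZT12 and ZT16, 144, 421, 49 and 14 in gi-2 and 359, 253, 187 and 225 in aba1-6. Each of these counts rests on 2 against 2 libraries and moved by more than 1.5 times when 1 of the 4 was left out. In wild type it was 382 at ZT1 without drought replicate 2, 547 at ZT8 without normal replicate 1 and 235 at ZT16 without normal replicate 1, and 1549 at ZT16 without drought replicate 1. In gi-2 the lowest were 9 at ZT1 (without drought replicate 2), 26 at ZT8 (drought replicate 1), 2 at ZT12 (drought replicate 2) and 2 at ZT16 (normal replicate 1). In aba1-6 they were 75 (drought replicate 2), 33 (drought replicate 2), 15 (drought replicate 1) and 37 (normal replicate 2). With a replicate block within each genotype the wild-type counts at ZT8, ZT12 and ZT16 were 2414, 1857 and 1670. With only the compared libraries in the fit the 4 counts were 824, 838, 358 and 147 in wild type, 626, 1368, 473 and 283 in gi-2 and 700, 1198, 152 and 481 in aba1-6, so gi-2 had more calls than wild type at ZT8, ZT12 and ZT16 in that fit and fewer in the fit of all libraries. ABA-induced genes were called higher in 23, 21, 26 and 15 of 35 cases in wild type at the 4 times and in 6, 8, 16 and 13 cases in aba1-6. Their medians in gi-2 were 0.08, 0.13, 0.37 and 0.42, against 1.09, 0.96, 1.62 and 1.07 in wild type and 0.53, 0.66, 1.23 and 1.15 in aba1-6. Compared with wild type, gi-2 differed for 341, 227, 856 and 1091 genes under normal watering and for 1125, 1017, 2185 and 1530 under drought. Leaving out 1 of the 4 libraries gave 119 to 211, 83 to 97, 482 to 680 and 516 to 920 genes under normal watering, and 452 to 1089, 429 to 997, 1139 to 2596 and 788 to 2690 under drought. With only the compared libraries in the fit the ZT12 count was 564 under normal watering, and the ZT12 and ZT16 counts were 892 and 323 under drought.

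**Figure D4:**
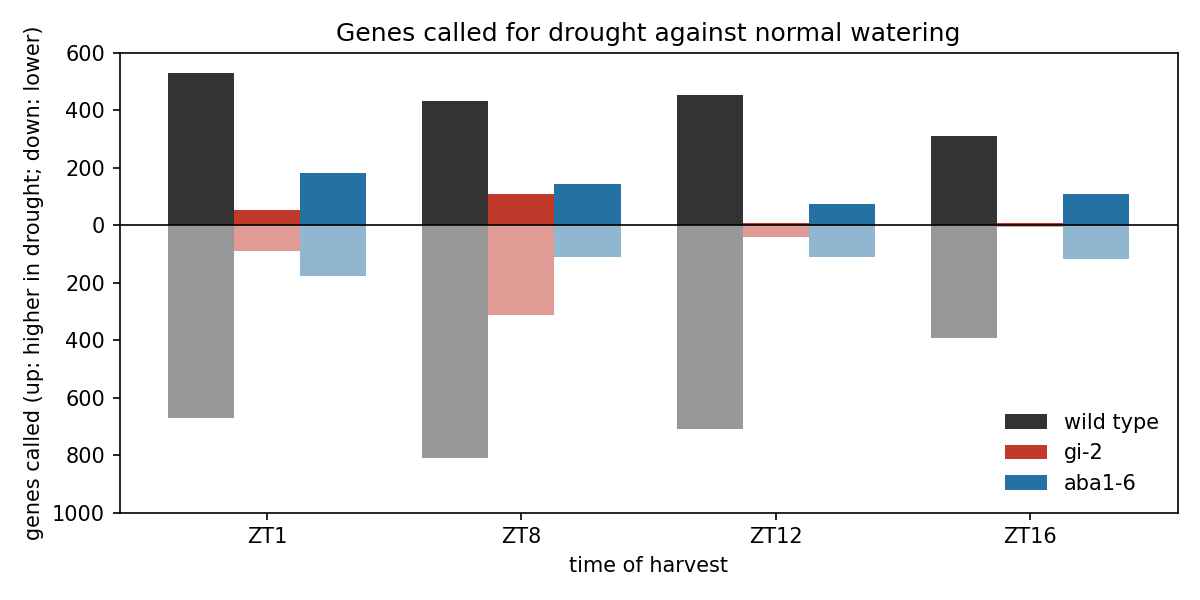
Number of genes called by edgeR between drought and normal watering in wild type, gi-2 and aba1-6 at the 4 times; bars above 0 are genes higher in drought and pale bars under 0 are genes lower in drought. Wild type had 704 to 1244 called genes per time and gi-2 14 to 421, but 147 to 838 and 283 to 1368 with only the compared libraries in the fit.

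Calls were shared between the mutants, which were compared with the same wild-type libraries. Under normal watering 613 genes were called in the same direction in gi-2 and aba1-6 (261 higher, 352 lower) and 296 in opposite directions. Independent lists would give 202.9 and 207.7, and simulated unchanged mutants gave a mean of 0.05 shared calls. Such mutants had a median of 0 calls in both regimes, so the simulated overlap gives no chance level for lists of this size. The simulation also drew the error of the wild-type mean independently at each time, so it leaves out deviations that same-numbered wild-type libraries share across times. The covariance of the fold changes was 0.0405, against the 0.0502 that the shared libraries alone gave in simulation. Where the mutants shared no wild-type library, it was 0.0307, or 0.0203 with the replicates exchanged. The simulated value therefore does not show that the shared libraries made the covariance. With different wild-type replicates for each mutant, 245 genes were shared in the same and 286 in the opposite direction, or 230 and 242 with the replicates exchanged, against 133.7 and 134.9, or 137.9 and 135.8, for independent lists. Sharing in opposite directions thus lay above the independent lists as well. Under drought 1980 were called in the same direction (1026 higher, 954 lower) and 264 in opposite directions, against 618.2 and 618 for independent lists and a simulated mean of 0.01. There the covariance was 0.136, against 0.0401 in simulation, and 0.127, or 0.117 exchanged, without shared wild-type libraries. With split controls the numbers were 1264 and 423, or 986 and 637 exchanged, and independent lists gave 584.4 and 570.1, or 608.3 and 618.4. Drought effects themselves, which share no libraries between genotypes, were called in the same direction for 574 genes in wild type and gi-2 (22 opposite, 117.5 same for independent lists), 1199 in wild type and aba1-6 (28 opposite, 206.9 same) and 444 in gi-2 and aba1-6 (6 opposite, 48.2 same).

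Guard cell markers did not pass in any contrast averaged over times (camera). With fry they passed as higher than in wild type in gi-2 (fry adjusted p = 0.00103 under normal watering and 0.000582 under drought). In aba1-6 they did so as well (fry adjusted p = 0.00081 and 4.44e-06). For the wild-type drought effect 1 of 5 was higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.746), the latter KAT1, a potassium channel gene (-0.74 ± 0.09 SE). That list's median was slightly positive and its mean and test negative, while for aliphatic glucosinolate genes the median was slightly negative and the mean and test positive. Reference genes gave 2 of 7 lower with drought in wild type (1 higher and 2 lower adjusted over the list alone, median -0.15, camera adjusted p = 0.173, but fry adjusted p = 0.000537), and ACT2 (actin) went from 920 to 684 CPM. Aliphatic glucosinolate genes gave 1 of 12 higher with drought in wild type (1 adjusted over the list alone, camera adjusted p = 0.746). Proline and raffinose-family genes gave 5 of 12 higher and 2 lower with drought in aba1-6 (6 and 2 adjusted over the list alone, median 0.23, camera adjusted p = 0.000232, adjusted p = 0.129 with an estimated correlation), with P5CS1 higher and ERD5, a proline breakdown gene, lower (-1.15 ± 0.16).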

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

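Some checks were chosen after the results they bear on had been seen. They are the comparison of replicate series and the tests of a milder water deficit in gi-2, of splits that part same-numbered libraries and of a changed stretch around HEI10. Differences of the drought effect between groups, tested as such, come first, followed by single genes that differed between genotypes and by splits of the libraries. The differences cover 1325 genes for gi-2 against wild type, 522 for aba1-6 against wild type and 156 whose drought effect in wild type differed between times.

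For gi-2 against wild type, the lists whose drought effect differed by camera were ABA-induced genes (median -0.99), ABA receptors and SnRK2 kinases (0.28, camera adjusted p = 0.0269, but 0.0563 with a replicate block within each genotype, 0.0687 without the 2 shallowest libraries, lost without any 1 of 8 libraries and 0.105 without gi-2 normal ZT12 replicate 2), proline and raffinose-family osmolytes (-0.14, camera adjusted p = 0.0224, 0.0506 without the filter on low counts, lost without any 1 of 5 libraries and 0.119 without wild-type normal ZT12 replicate 2) and flavonoid synthesis (-0.67). For the receptor list adjusted p = 0.429 with an estimated correlation, for the osmolyte list adjusted p = 0.52 and for the flavonoid list adjusted p = 0.429. Genes with a higher log2 drought effect in gi-2 were GASA1 (2.16), AZI1 (1.96, edgeR adjusted p = 0.0644 without wild-type drought ZT16 replicate 1), PUP18 (1.83), AT3G16670 (1.75), XTH6 (1.59), AT4G09420 (1.45), BXL1 (1.45), AT5G60270 (1.41), PYL4 (1.25) and RBCS1B (0.58). Genes with a lower one were AT2G37870 (-3.58), AT3G53980 (-2.91), AT4G33550 (-2.84), HAI2 (-2.83), AT5G48650 (-2.75), AT4G33905 (-2.65), HAI1 (-2.24), AFP1 (-2.14), GOLS2 (-1.73), PP2CA (-1.19), RD29A (-1.15) and NCED3 (-0.95). It was lower as well for AT4G08570 and AT5G40800, where both libraries of a group stood at 0 counts at 1 or more of the times, so their fitted -5.14 and -4.06 are no estimates of size. Their levels went from 0.37 to 11.98 and from 0.74 to 8.94 CPM in wild type, and from 0.65 to 2.43 and from 1.36 to 2.57 CPM in gi-2. The call of AT4G08570 was lost without gi-2 normal ZT8 replicate 1 (edgeR adjusted p = 1).

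For aba1-6 against wild type, the list medians were -0.27 for ABA-induced genes, -0.91 for flavonoid synthesis, 0.12 for photosynthesis, 0.91 for carbon starvation and 0.31 for salicylic acid and defence. With an estimated correlation none of these 5 passed, and their adjusted p = 0.687, 0.188, 0.756, 0.4 and 0.756 with an estimated correlation. The photosynthesis and the defence call were each lost without any 1 of 5 libraries, at most to camera adjusted p = 0.284 without wild-type drought ZT12 replicate 2 and 0.101 without aba1-6 drought ZT12 replicate 2. Without the 2 shallowest libraries the photosynthesis list gave 0.426, and with a filter at 5 CPM the carbon starvation list gave 0.205 (camera adjusted p). The carbon starvation call was lost without wild-type drought ZT16 replicate 1 (0.0554) or aba1-6 drought ZT1 replicate 1 (0.404). Genes with a higher log2 drought effect in aba1-6 were AT5G20790 (4.27), MGDC (3.36), PS2 (3.12) and PYL4 (0.84). It was higher as well for CIB1, pEARLI_1, AT1G23110, AT5G62730 and FLS5, where both libraries of a group stood at 0 counts at 1 or more of the times, so their fitted 5.53, 5.40, 5.07, 4.78 and 3.13 are no estimates of size. CIB1 went from 8.58 to 8.33 CPM in wild type and from 5.04 to 10.9 in aba1-6, pEARLI_1 from 27.05 to 0.09 and from 16.9 to 2.53, and AT1G23110 from 1.91 to 0.5 and from 1.55 to 7.27. AT5G62730 went from 2.46 to 0.12 CPM in wild type and from 6.37 to 5.03 in aba1-6, and FLS5 from 3.58 to 0.28 and from 5.04 to 1.95. Genes with a lower one were TT8 (-1.76), MEE25 (-1.76), AT5G48650 (-1.69), MGL (-1.34), AT3G57540 (-1.23), SWEET4 (-1.08), AT5G47550 (-1.06), AT1G62290 (-1.04), UGT75C1 (-0.97) and PP2CA (-0.53). Several of these calls depend on single libraries. They were lost without any 1 of 23 libraries for PYL4 (edgeR adjusted p up to 0.117 without wild-type drought ZT12 replicate 2) and AT5G48650 (0.231, aba1-6 normal ZT8 replicate 2). For TT8 and AT5G47550 it was any 1 of 20 (0.0894, aba1-6 normal ZT12 replicate 2, and 0.117, aba1-6 normal ZT1 replicate 1), for MGL any 1 of 7 (0.103, aba1-6 normal ZT8 replicate 2), and for CIB1 and AT1G23110 any 1 of 3 (1, wild-type normal ZT12 replicate 2, and 0.0952, wild-type normal ZT8 replicate 1). A single library ended the call of pEARLI_1 (0.301, aba1-6 drought ZT16 replicate 2), PS2 (0.0633, wild-type normal ZT12 replicate 2), SWEET4 and AT1G62290 (0.143 and 0.0879, aba1-6 normal ZT1 replicate 1) and PP2CA (0.0523, wild-type drought ZT1 replicate 2).

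The smaller drought effect on ABA-induced genes in gi-2 was not made by the library with conflicting labels: without it the median difference was -1.043 and 26 members were lower. The pattern was seen with both replicate series of wild type. The smaller wild-type rise of the list (1.06 on the log2(CPM + 1) scale) exceeded the larger gi-2 rise (0.42) by 0.64. These rises do not test a shift between the series, because such a shift cancels from drought minus normal within a replicate number. In gi-2 the replicate numbers did not pair libraries. A milder water deficit in the gi-2 plants may account for part of the pattern and stays open. The slope of gi-2 on wild type, over genes chosen by their wild-type call, was 0.27 (95% interval 0.17 to 0.40) for the 31 called list members and 0.21 (0.17 to 0.24) for the other genes that rose, but 0.67 (0.62 to 0.71) for those that fell. The 31 list members include ANAC019, which fell in wild type and in gi-2, so their slope is not one of rises alone. The intervals come from resampling genes, so they do not measure the spread between libraries. The slope for genes that fell also includes genes with a group at 0 counts, whose fitted fold changes are no estimates of size. A biological effect of GI on the response also stays open and cannot be told apart from the milder deficit, because tissue water status is not given in the sources used here.

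HEI10 and MRD1 were nearly absent in gi-2. They overlap by 1446 bases on chromosome 1 (MRD1 19963047 to 19964712, HEI10 19963267 to 19966952, TAIR10.1), so without strand, reads in the shared part cannot be told apart. Of the 9 other nearest tested genes, 0 were called by edgeR with at least a 2-fold change in both watering regimes; MUM4, the next gene, had log2 fold changes of 0.01 and 0.00. A changed stretch of chromosome 1 in the gi-2 line that covers both genes and ends before MUM4 may be present, and levels alone do not decide it. No biological explanation was tested.

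AT3G01345 was high in aba1-6 in both regimes (262.24 and 240.6 CPM). Of its 10 nearest tested genes, 0 were called by edgeR with at least a 2-fold change in both regimes. The change in level was thus not shared by its neighbours. A differing stretch of chromosome 3 need not change the levels of all its genes, so levels alone do not decide whether one is present. One neighbour, AT3G01319, was higher under drought alone (log2 fold change 1.32, edgeR adjusted p = 0.0143). A differing stretch around the gene, a change of the gene itself in the line, or an effect of aba1-6 on it stays open.

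Whether other groupings of the libraries give as many genes was tested with 100 splits within times, the real one included, using the compared libraries alone. In each of the 9 time-averaged comparisons 1 of 100 splits, the real one, gave as many genes. The splits treat the libraries of a time as exchangeable, although same-numbered wild-type libraries deviate together. The real and the highest other count were 2444 and 1066 for drought in wild type, 1995 and 530 in gi-2, 2533 and 511 in aba1-6, 2325 and 1090 for gi-2 against wild type under normal watering and 4095 and 1837 under drought. For aba1-6 they were 2836 and 518, and 3208 and 770. For the difference of drought effects they were 1040 and 751 for gi-2, and 305 and 299 for aba1-6. The median count of the other splits was 0 in each comparison. A split that mixes the real groups holds their difference as spread, which lowers its count. The splits therefore cannot exclude chance. For the differences of drought effects the splits exchanged genotype labels, so they also broke up the plain difference between genotypes. The margin for the aba1-6 difference was small. For drought in wild type, where the numbers pair the libraries, 100 splits that part all 8 same-numbered pairs, as the real one does, gave at most 1066 genes apart from the real 2444. Splitting wild type by replicate number, which keeps those pairs together, gave 705 genes.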

How the results depend on the processing

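The block per genotype and the fit without the 2 shallowest libraries were chosen after seeing the data. Of 691 results for 194 named genes, all 691 kept direction and side of the threshold with DESeq2 size factors, and with DESeq2 as the test 3 were lost and 12 gained. With library totals 7 were lost and 3 gained, without the filter 6 and 56, with a mean of at least 5 CPM 1 lost of 543, with only the compared libraries 30 and 25, with the planned replicate block 2 and 2, with the block per genotype 6 and 16, and without the 2 shallowest libraries 16 and 8. Leaving out each library in turn, 472 of 11408 values were lost, 54 gained and 1 reversed: LHY in gi-2 under normal watering, -1.28, which was 0.24 without wild-type normal ZT12 replicate 2 and lowest, -2.23, without gi-2 normal ZT12 replicate 2. In both of these LHY fits the library left in the ZT12 group stood at 0 counts, so neither value is an estimate of size. Of 180 list results, 40 were lost with an estimated correlation, and fry lost 7 and gained 26. Library totals lost 1 and gained 2, the filter at 5 CPM lost 6 and gained 2 of 171 (no floral marker passes it), no filter lost 2 and gained 6, the block per genotype lost 6 and gained 2, the 2 shallowest libraries left out lost 6 and gained 5, and the planned block gained 1. No list turned its direction in a call. For ABA-induced genes the calls lost with an estimated correlation were drought in gi-2 (0.246), gi-2 against wild type under normal watering (0.194) and drought (0.121), and the difference for aba1-6 (0.687, and 0.198 with fry). The median of all genes moved by at most 0.1 under each scaling.

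The fit of all libraries shares its estimate of each gene's spread across groups. Replicate counts differed by 11.57 to 13.8 times the variance of sampling noise in wild type under drought. In gi-2 under drought it was 3.0 to 4.62 times. Counts of calls beyond 1.5 times the reported one were as follows, and their cause was not tested. With only the compared libraries: drought in wild type 2444, gi-2 1995, difference for aba1-6 305; drought at ZT12 and ZT16 in wild type 358 and 147; at ZT1, ZT8, ZT12 and ZT16 in gi-2 626, 1368, 473 and 283; at ZT1, ZT8 and ZT16 in aba1-6 700, 1198 and 481; gi-2 against wild type at ZT12 under normal watering 564 and at ZT12 and ZT16 under drought 892 and 323; drought by time 16. With the replicate block per genotype: drought in gi-2 1615, differences 2678 for gi-2 and 1510 for aba1-6; wild type at ZT8, ZT12 and ZT16 2414, 1857 and 1670; gi-2 at the 4 times 296, 815, 181 and 74; aba1-6 679, 740, 401 and 417. For gi-2 against wild type that block gave 732, 473 and 1701 at ZT1, ZT8 and ZT16 under normal watering and 1952, 1865 and 2636 under drought, and 520 for drought by time. The planned replicate block, common to all genotypes, moved no count by that much: drought in wild type gave 4642. Without the filter: difference for aba1-6 998, wild type at ZT16 1258, gi-2 at the 4 times 457, 833, 372 and 256, aba1-6 716, 698, 509 and 554, gi-2 against wild type under normal watering at ZT1 and ZT8 680 and 386, drought by time 704. Without the 2 shallowest libraries: wild type at ZT12 and ZT16 774 and 348, gi-2 at ZT12 and ZT16 88 and 25, aba1-6 at ZT8 398, gi-2 against wild type under drought at ZT16 841. With DESeq2: gi-2 at ZT12 and ZT16 124 and 70, drought by time 276. With library totals: gi-2 at ZT16 23.

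Leaving out each library in turn, with the lone library of a group assumed to vary like the other groups, gave these ranges. Time-averaged: drought in wild type 3395 to 5161, gi-2 642 to 904, aba1-6 1326 to 1683; gi-2 against wild type 1917 to 2290 and 4363 to 6157; aba1-6 2529 to 3102 and 3420 to 5095; differences 967 to 2006 and 309 to 833. Time of day gave 5796 to 7520 and drought by time 107 to 249. At ZT1, ZT8, ZT12 and ZT16, drought in wild type gave 382 to 931, 547 to 1140, 705 to 1170 and 235 to 1549, in gi-2 9 to 57, 26 to 224, 2 to 21 and 2 to 18, and in aba1-6 75 to 319, 33 to 93, 15 to 203 and 37 to 119. For gi-2 against wild type it was 119 to 211, 83 to 97, 482 to 680 and 516 to 920 under normal watering and 452 to 1089, 429 to 997, 1139 to 2596 and 788 to 2690 under drought. Shared calls of the mutants under normal watering, 613 in the same and 296 in opposite directions, were 28 and 24 at a 2-fold change and 245 and 230 in the same direction with split controls. Under drought, 1980 and 264 became 188 and 11 at a 2-fold change and 1264 and 423, or 986 and 637, with split controls. Counts at single times rest on 2 against 2 libraries, where the simulation at ZT1 recovered 31.3% of 1.5-fold, 79.1% of 2-fold and 97% of 4-fold changes. What depth limits was tested here only by leaving out the 2 shallowest libraries.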

Other observations

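The values at single times, the genes named with them and the tests under drought of the genes taken from aba1-6 were chosen after related results had been seen. Under normal watering, PRR7 had, in gi-2 against wild type, log2 fold changes of 0.23, 0.29, 1.53 and 3.13 at ZT1, ZT8, ZT12 and ZT16, and those at ZT12 and ZT16 passed (edgeR adjusted p = 1.05e-08 and 1.42e-15). PIF4 followed the same course with -0.08, 0.21, 1.74 and 3.09 (edgeR adjusted p = 7.23e-12 and 1.22e-17 at ZT12 and ZT16). Chalcone synthase (CHS, also TT4) went the other way with -0.47, -0.79, -3.79 and -4.03 (edgeR adjusted p = 1.06e-06 and 7.27e-08). Other genes took other courses. GI passed at each time, and the heat shock gene HSP101 had -0.81, -0.40, -1.19 and -0.67, of which those at ZT1, ZT12 and ZT16 passed (edgeR adjusted p = 0.00119, 7.6e-06 and 0.00691) and that at ZT8 did not (0.459). The ZT1 call was lost without 2 libraries, at most to edgeR adjusted p = 0.0798 without gi-2 normal ZT1 replicate 1. The ZT16 call was lost with only the compared libraries (0.0578) and without any 1 of 3 libraries, at most to 0.144 without wild-type normal ZT16 replicate 2. CCA1, a morning gene, stood at 274.5 against 425.4 CPM at ZT1 (-0.63, edgeR adjusted p = 0.0827, which passed with a replicate block within each genotype) and was higher at ZT12 (1.82, edgeR adjusted p = 0.0223, 0.0504 with library totals as the only scaling, 0.211 with only the compared libraries, lost without any 1 of 3 libraries and 0.474 without wild-type normal ZT12 replicate 2) and ZT16 (2.15, edgeR adjusted p = 7.5e-05). ABA1 was higher at ZT12 and ZT16 (1.38 and 0.95, edgeR adjusted p = 3.47e-06 and 0.000474). Whether the gap differs between times was not tested.

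A hypothesis was that genes that rise in drought are already higher in gi-2 without drought. It was tested on the 764 genes that rose in aba1-6, which share no library with the comparison. In gi-2 against wild type under normal watering their median log2 fold change was 0.016, with 154 higher and 119 lower. Among all 19037 tested genes 1351 were higher and 1068 lower, a smaller share in each direction. By camera p = 0.457 with an estimated correlation and 0.183 with the preset one, so the hypothesis was not borne out for this set. The ABA-induced list passed as higher there with the preset correlation and not with an estimated one (camera adjusted p = 0.194). Under drought the 764 genes were lower in gi-2, with a median of -0.132 and limma's camera test at p = 0.00298 with an estimated correlation (99 higher, 280 lower). The 1011 genes that fell in aba1-6 were higher in gi-2, with a median of 0.31 and limma's camera test at p = 0.000134 with an estimated correlation (495 higher, 52 lower).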
